A study of Oryctolagus cuniculus with 6 samples.

How the data were processed

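Bulk RNA sequencing of rabbit (Oryctolagus cuniculus) trachea on day 14 was compared between 3 blank and 3 hydrogel libraries, grouped and numbered by their titles. Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase and checked for integrity, then fragmented, copied to double-stranded cDNA, ligated to adapters and amplified by PCR.

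The deposited counts are whole-number read counts per gene for 16815 Ensembl rabbit identifiers, and the 6 tables per sample held the same values as the series table. Per the submitters' processing notes, the tools named were FastQC 0.11.9, Trimmomatic 0.39, HISAT2 2.2.1, featureCounts 2.0.2, DESeq2 1.34.0 and GATK 4.3.0.0. The same notes name the human build GRCh38 and the mouse build mm10. The rabbit build, the annotation and the strand setting of the counting are not given in the sources used here. Overlapping genes and near-identical copies may therefore share reads. Tables that carry the name FPKM hold a deposited signal: within a relative tolerance of 1e-06, 100% of values equal the count divided by 1 factor per library, without gene length. These factors equal the size factors that DESeq2 gives on the counts, for example 1.0646 for blank replicate 1. The tables were not used as FPKM. The authors' deposited comparison table gives log2 fold changes with standard errors, p-values and adjusted p-values. A DESeq2 repeat gave the same 1019 genes with an adjusted p under 0.05 and an absolute log2 fold change above 2, with log2 fold changes within 4.16e-09. The authors' deposited enrichment tables list 27 GO and 14 KEGG terms with their genes, in 4 clusters, and 4 terms carry a gene ratio stored as a date. Per the file headers, 2 further tables give interval estimates of group differences. Each of the 6 deposited workbooks has 67 sheets, 66 of them identical in all 6, and 61 were not used. Another 468 columns of numbers per workbook were not matched to a sample and not used.

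Counts were tested with edgeR 4.0.16 (quasi-likelihood fit, TMM scaling, filterByExpr by group) in R 4.3.3, with group as the term and Benjamini-Hochberg adjustment over the 13598 genes kept, at a threshold of 0.05 and with no fold threshold. The common biological coefficient of variation was 58.5%. The standard error of a log2 fold change was taken from the fold change and its F statistic and is approximate. Log2 CPM used a prior count of 2. The level of a term is the geometric mean CPM of its tested genes in each library. Terms with at least 4 genes were described, 37 in all. For a gene at 0 in a whole group, the fold is against a floor of 3 counts per library. The test was checked on 3 simulated data sets with the same 13598 genes and 200 changed genes. It recovered 41.7% of genes changed 4-fold and 77.7% of genes changed 16-fold, and 3.76% of its calls were false. The changed genes were taken from genes above a minimum mean level. Counts were drawn independently for each gene, with the same dispersion in both groups. In the data 865 genes were called, and the median SD of log2 CPM within groups was 0.488 in blank and 0.373 in hydrogel. The simulated shares therefore need not hold for the data. Alternatives used DESeq2 1.42.0 and limma 3.58.1, other scalings and filters, a fold threshold, the replicate number as a block, and each library left out. Figures were drawn with matplotlib 3.10.9.

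Of the 16815 identifiers, 0 matched the reference gene table (assembly mOryCun1.1), so none has a symbol here. The 45 gene lists of airway cell types, tissues, pathways and RNA quality fixed before the data were examined, their camera and fry tests, the cell type markers and the panel of symbols could not be used. The rule for named genes, fixed at the same time, took the 8 genes with the largest fold change in each direction among those with a symbol, an adjusted p under 0.05, an average log2 CPM of at least 1 and no overlap between groups. Without the symbol condition, 598 higher and 251 lower genes met it, and the first 2 identifiers in each direction are given. The terms were taken from the authors' deposited tables after the data were seen. Deposited measurements of human tissue were not used.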

Results

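RNA was sequenced from rabbit trachea collected on day 14 in 2 groups of 3 libraries. The blank group had an epithelial defect and no further treatment, and the hydrogel group had the same defect and received the LA@PA-TA@C hydrogel. The design text calls the 3 libraries of a group biological replicates. The deposited counts covered 16815 genes, of which 16378 had at least 1 count. Total counts were 23390531, 21081843 and 17292087 in blank replicates 1, 2 and 3, and 22309570, 23095010 and 16827419 in hydrogel replicates 1, 2 and 3. The depth ranges of the groups therefore overlapped. The genes are known here by Ensembl rabbit identifiers alone, because none could be paired with a symbol, so gene groups are described through the terms listed in the authors' deposited enrichment tables.

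The comparison of hydrogel with blank asks how the transcriptome of the injured trachea differed with the hydrogel in place. Among genes listed under cilium terms in the authors' deposited tables, 14 of 20 rose in hydrogel tracheae. Among those listed under terms of metabolism, respiration, mucin-type glycosylation, Parkinson's disease and Huntington's disease, 43 of 71 rose. Among tested genes listed under terms of extracellular matrix, adhesion, vessels, inflammation and related processes, 50 of 133 fell and 83 did not pass. Of 13598 genes tested, 865 changed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 610 higher and 255 lower in hydrogel. The count rested on single libraries: it was 532 without blank replicate 3, 501 without hydrogel replicate 1, 7 without hydrogel replicate 2 and 11 without hydrogel replicate 3. In each fit without 1 library, all 865 genes kept their direction and an unadjusted p under 0.05 (edgeR quasi-likelihood test). What many of them lost was the adjusted threshold. The 865 were chosen with all 6 libraries, so this is not independent evidence. DESeq2 called 2104 genes on the same counts, 1281 higher and 823 lower.

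The authors' terms were chosen on these samples, from genes that already differed, so the counts given for them are not independent evidence of direction, of size or of passing a test. Each list holds only the genes of a term that the authors placed in 1 cluster, not the whole term: 12 of the 65 oxidative phosphorylation genes in their background, for example. Counts below are of listed genes. Many genes are listed under several terms, so the terms are not separate findings. Every tested listed gene had a log2 fold change in the direction of its term's cluster, which follows from that choice. That all listed genes passed with DESeq2 follows from it too, because the authors' comparison was made with that test.

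Cilium movement had the largest median difference of the terms with at least 4 genes. Of its 6 listed genes, 4 rose and 2 did not pass, with a median log2 fold change of 5.33. Their geometric mean level was 3.10 ± 3.94 CPM (counts scaled to library size) in blank and 102 ± 40.7 CPM in hydrogel (SD, n = 3). Blank replicate 1 was at 7.64 CPM, against 0.707 and 0.945 CPM in blank replicates 2 and 3. Hydrogel replicate 1 was at 55.9 CPM, against 132 and 118 CPM in hydrogel replicates 2 and 3. Of the 14 listed genes of cilium assembly, the building of the axoneme-based organelle, 10 rose and 4 did not pass. Their level was 12.4 ± 5.54 CPM in blank and 84.5 ± 35.5 CPM in hydrogel (SD, n = 3). Of 5 listed genes of non-motile cilium assembly, 3 rose, with a median log2 fold change of 2.01. Of these 5, 4 are also listed for cilium assembly. Over the 20 distinct genes of these terms, 14 rose; the number was 6 with limma-voom, 7 without blank replicate 2, 4 without blank replicate 3, and 0 without hydrogel replicate 2 or without hydrogel replicate 3.

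All 12 listed genes of oxidative phosphorylation, a term that includes the mitochondrial respiratory chain and ATP synthase, rose in hydrogel, with a median log2 fold change of 1.45. They held 1.45 ± 0.225% of all counts in blank and 4.60 ± 0.446% in hydrogel (SD, n = 3), and 2 of them were among the 10 most abundant genes. Of 13 genes listed for Parkinson's disease, out of 77 in the authors' background, 11 rose, and 10 of the 13 are also listed for oxidative phosphorylation. Of 14 genes listed for Huntington's disease, out of 102, 11 rose, and 5 of the 14 are also listed there. Of 38 listed genes of oxidation-reduction process, 22 rose, and the level went from 17.4 ± 3.05 CPM in blank to 90.5 ± 6.16 CPM in hydrogel (SD, n = 3). Of 8 listed genes of glutathione metabolism, the cell's main thiol antioxidant system, 7 rose, with a median log2 fold change of 1.68.

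Mucin type O-glycan biosynthesis includes the attachment of the first sugars to mucins. Of its 8 listed genes, 3 rose and 5 did not pass, at a median log2 fold change of 2.64 and levels of 5.97 ± 4.11 CPM in blank and 47.0 ± 4.89 CPM in hydrogel (SD, n = 3). Of 8 listed genes of PPAR signaling, a lipid-sensing nuclear receptor pathway, 3 rose, with a median log2 fold change of 2.77. Over the 71 distinct genes of the metabolic, glycosylation, Parkinson's disease and Huntington's disease terms, called metabolic-term genes below, 43 rose. The number was 71 with DESeq2, 23 without hydrogel replicate 1, 1 without hydrogel replicate 2 and 0 without hydrogel replicate 3.

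**Figure D1:**
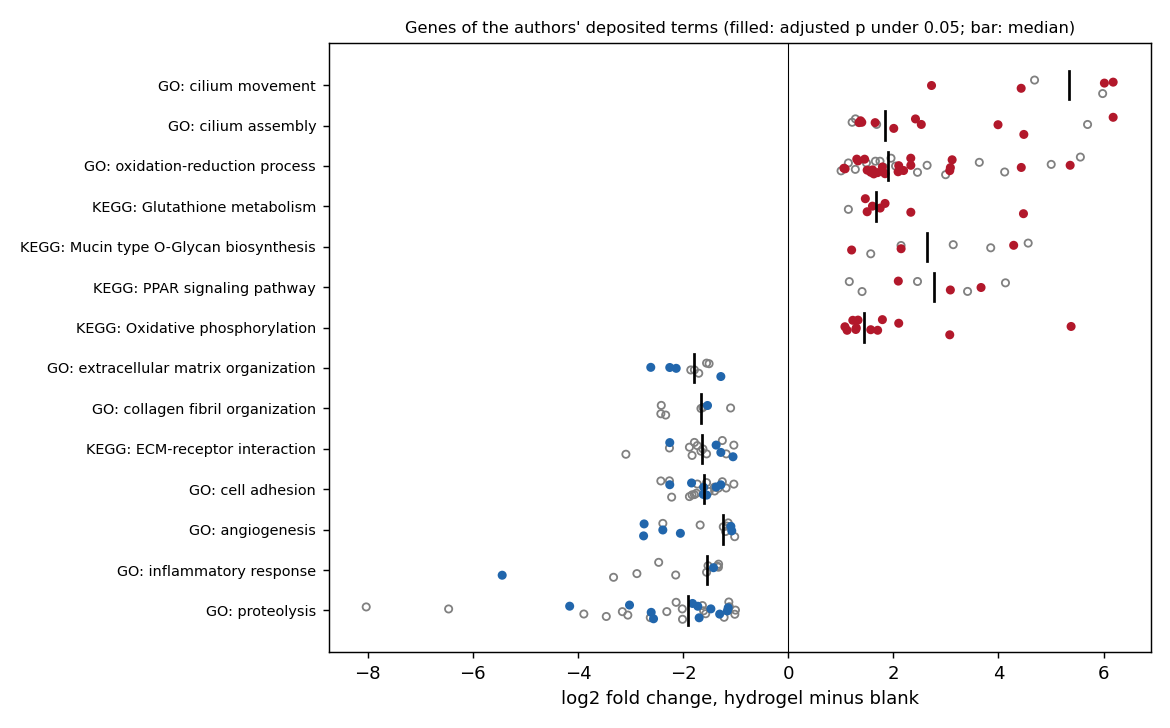
Log2 fold change (hydrogel minus blank, horizontal axis) of each tested gene of 14 terms from the authors' deposited enrichment tables; filled points passed the edgeR test at an adjusted p under 0.05, open points did not, and bars are medians. The median of cilium movement lies at 5.33 and that of proteolysis at -1.91.

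Of 9 listed genes of extracellular matrix organization, 4 fell, and the level was 172 ± 56.4 CPM in blank and 50.6 ± 7.61 CPM in hydrogel (SD, n = 3). Of 16 listed genes of ECM-receptor interaction, 4 fell and 12 did not pass, at 437 ± 175 CPM in blank and 145 ± 1.67 CPM in hydrogel (SD, n = 3). Of these 16, 11 are also listed for cell adhesion. Of 23 tested listed genes of cell adhesion, 7 fell, with a median log2 fold change of -1.61. Of 7 listed genes of collagen fibril organization, 1 fell and 6 did not pass, at a median of -1.66 and with blank levels from 1016 to 3086 CPM. Of 4 listed genes of cartilage condensation, 1 fell, at a median of -2.35. Of 30 listed genes of proteolysis, 11 fell, at a median of -1.91.

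Of 13 listed genes of angiogenesis, 6 fell, with levels of 83.7 ± 22.8 CPM in blank and 25.1 ± 3.44 CPM in hydrogel (SD, n = 3). Of 12 listed genes of positive regulation of angiogenesis, 4 fell, at a median log2 fold change of -2.22. All 5 listed genes of negative regulation of endothelial cell apoptotic process fell, at a median of -2.38. The term has 17 genes in the authors' background, and 4 of the 5 are also listed for angiogenesis. Of 11 listed genes of inflammatory response, 2 fell and 9 did not pass, at 77.9 ± 32.0 CPM in blank and 17.6 ± 5.11 CPM in hydrogel (SD, n = 3). None of the 6 listed genes of cellular response to interleukin-1 passed over all genes tested, although all 6 passed with DESeq2 and when adjusted over the list alone, which is not independent evidence because the list was chosen on these samples. Over the 136 distinct genes listed under the authors' cluster of these terms, 133 were tested and 50 fell; the number was 136 with DESeq2, which tested all of them, 102 with quality weights, 31 without blank replicate 1, 23 without blank replicate 3, 18 without hydrogel replicate 1, and 0 without hydrogel replicate 2 or without hydrogel replicate 3.

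**Figure D2:**
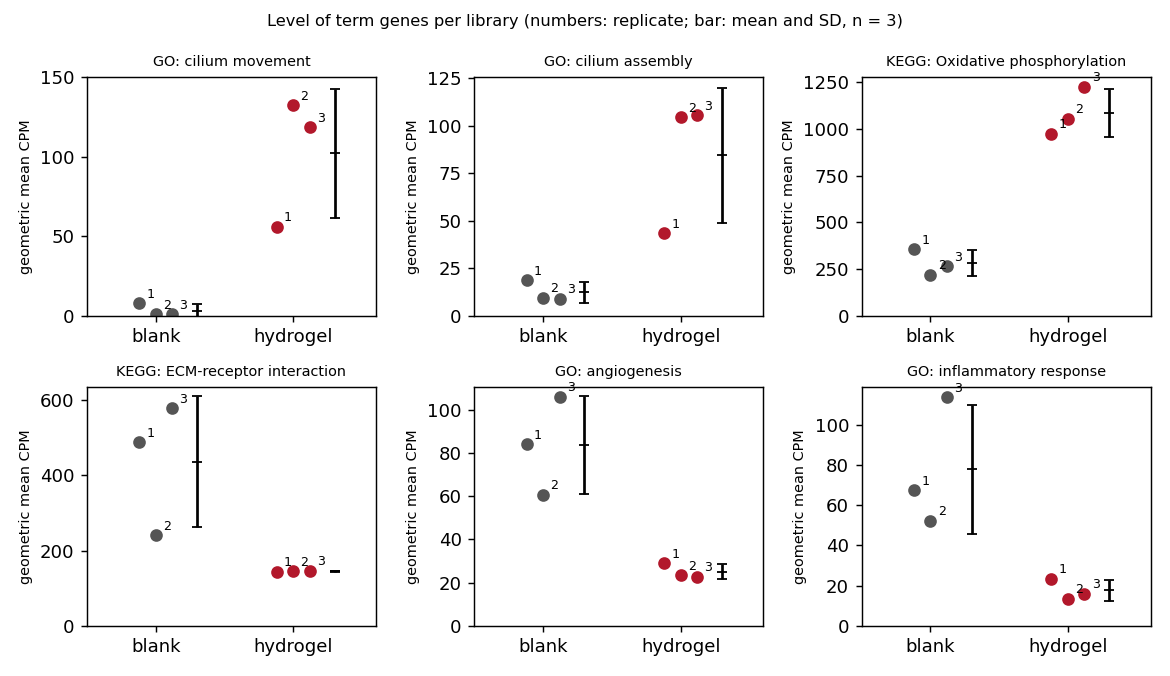
Geometric mean level (CPM, vertical axis from 0) of the genes of 6 terms in each library, with replicate numbers beside the points and the mean and SD of each group (n = 3) as bars. The groups do not overlap in any of the 6 panels, which was likely in advance because the authors chose these genes for differing between these libraries. In cilium movement blank replicate 1 (7.64 CPM) lies above the other blanks.

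Among single genes, those with the largest fold change that also passed the test, averaged at least 1 on the log2 CPM scale and did not overlap between groups were taken. ENSOCUG00000021932 had no count in any blank library and 11.4 ± 7.46 CPM in hydrogel (SD, n = 3), at least 75.2-fold higher than a floor of 3 counts per library (edgeR adjusted p = 0.0256). ENSOCUG00000006891 also had no count in blank and 7.83 ± 3.09 CPM in hydrogel (SD, n = 3), at least 51.8-fold higher (edgeR adjusted p = 0.0240). ENSOCUG00000021580 was at 20.9 ± 7.36 CPM in blank and had 2 counts over the hydrogel libraries, a ratio of blank to hydrogel of 632 (exact 95% Poisson interval 175 to 5227, edgeR adjusted p = 0.00708). ENSOCUG00000024282 fell from 80.2 ± 28.7 to 0.209 ± 0.0727 CPM (SD, n = 3), a log2 fold change of -8.56 with an approximate standard error of 0.468 (edgeR adjusted p = 0.000965). The calls of the first 3 ended without hydrogel replicate 2 and without hydrogel replicate 3, and that of ENSOCUG00000006891 also without hydrogel replicate 1. With limma-voom, the calls of ENSOCUG00000021932 and ENSOCUG00000024282 ended, and with quality weights that of ENSOCUG00000021932. Intervals and floors cover counting error only.

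The authors' deposited differential expression table listed 1019 genes, 791 higher and 228 lower in hydrogel. Of these, 959 were tested here and 481 were called by edgeR, 410 higher and 71 lower. The 481 became 255 with limma-voom, 317 without blank replicate 2, 303 without hydrogel replicate 1, 7 without hydrogel replicate 2 and 11 without hydrogel replicate 3. With DESeq2 all 1019 passed, which was given in advance, because the authors' table was made with that test. In the authors' deposited table of transcript comparisons, on a relative scale whose assay was not stated, blank minus hydrogel was 0.822 for VWF, a vessel marker (95% interval 0.537 to 1.108), and 0.589 for Col I, a fibrillar collagen (0.3035 to 0.874). It was 0.659 for SPP1 (0.374 to 0.945), 0.494 for IGF1 (0.209 to 0.780) and 0.683 for SOX9, a cartilage transcription factor (0.398 to 0.969). In the authors' deposited table of section measurements, whose units were not stated, the intervals for blank minus hydrogel excluded 0, with hydrogel higher for PAS, AC-Tub and CK14 and blank higher for thickness and for a further measurement without a title.

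Libraries of one group correlated more with each other than with the other group, across genes. Pearson's r of log2 CPM, over genes that are not independent replicates, was 0.842 to 0.881 between blank libraries, 0.863 to 0.942 between hydrogel libraries and 0.685 to 0.833 between groups. The first principal component held 54.7% of the variance. Blank libraries lay at -31.08, -75.57 and -159.68 on it, and hydrogel libraries at 67.84, 95.94 and 102.55.

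**Figure D3:**
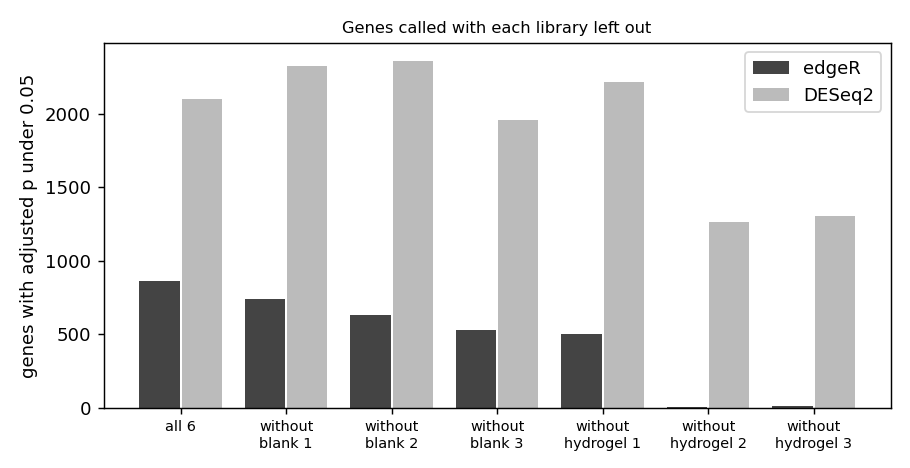
Number of genes with an adjusted p under 0.05 (vertical axis from 0) in edgeR (dark bars) and DESeq2 (light bars), with all 6 libraries and with each library left out. The edgeR count falls from 865 to 7 without hydrogel replicate 2 and to 11 without hydrogel replicate 3, where DESeq2 calls 1266 and 1305 genes.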

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

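Thinning libraries to the smallest total, quality weights and the authors' limits were chosen after seeing the data. The 3 counts (all, higher, lower) stayed within 1.5 times under DESeq2 size factors (874), upper-quartile factors (886), no filter (911), a stricter filter (899), a fold threshold (807), library sizes without the 10 highest genes (866), limma-voom (609), thinning (902) and the authors' limits in DESeq2 (1019). Only 481 of the 1019 were among the 865, so the similar total there is not a similar set of genes. With the DESeq2 test the 3 counts were 2104, 1281 and 823, including 864 of the 865. All 136 genes of the terms lower in hydrogel and all 71 metabolic-term genes passed it. That follows from the choice of the lists, because the authors' comparison was made with DESeq2 on these samples. Limma-voom left 6 cilium-term genes. Quality weights gave 1694 genes, 792 lower, with 102 of the lower-term genes. The cause of the other differences was not tested.

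Leaving out 1 library gave 7 to 741 genes in all, 5 to 603 higher and 2 to 246 lower. It gave 0 to 56 lower-term, 0 to 33 metabolic-term and 0 to 13 cilium-term genes. The 2 lowest counts came without hydrogel replicate 2 (7) and 3 (11). With the replicate block, the counts were 15, 10 and 5, and 0, 1 and 0 for the lower, metabolic and cilium terms, and 3 of the 4 identifiers were no longer called. Same-numbered libraries did not deviate together (correlations -0.20, 0.01 and -0.10). With 3 libraries per group these values cannot decide whether the numbers pair samples, and the labels do not say. Without a filter the lowest correlations were 0.892 between blank and 0.913 between hydrogel libraries, since genes near 0 enter. Of the term medians over 16 settings (all but the fold threshold and the authors' limits), 584 moved by less than the replicate spread, 8 by more, and 0 changed sign. Of the fold changes of the 4 identifiers, 59 kept their side of the threshold and 13 did not. The tests on FPKM values and of gene lists, with camera and fry, were not run, because no FPKM values and no symbols were at hand. The simulation, with 200 changed genes and counts drawn independently for each gene, recovered 41.7% of 4-fold changes, a share that need not hold for these data.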

Other observations

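All tests of explanations in this part were chosen after the results were seen. Some genes were near absent in one group. Under 0.1 CPM in every blank library and above 1 CPM in every hydrogel library were 43 genes, and 11 genes showed the opposite, while the highest number over the other splits of the libraries was 17. Of all tested genes, 32.8% did not overlap between groups. Chance gives 10% as an average over splits, but genes vary together, so the share in a single split can lie far from it. The share in the other splits was not computed. For further terms of the authors' deposited tables, whose lists were chosen on these samples, 10 of 27 listed genes of PI3K-Akt signaling fell, 3 of 9 of response to hypoxia and 1 of 6 of wound healing (edgeR, adjusted over all genes). Of the 27 PI3K-Akt genes, 15 are also listed for ECM-receptor interaction.

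The 6 libraries can be split into 3 and 3 in only 10 ways, too few for a share under 0.05. The real split was the 1 split with as many genes as 865 in all, 610 higher, 255 lower, 50 lower-term genes, 43 metabolic-term genes and 14 cilium-term genes. The highest count over the other splits was 0 in each case with edgeR. Each of those splits put libraries of both groups on each side, so a difference between the groups would widen the spread within sides. Few or no calls there were therefore likely in advance, and the 0 does not measure what chance gives. The 3 term counts add nothing to the count of all genes. Their lists were chosen on the real split, and no gene at all was called in the other splits. Those splits had 117 to 734 genes at an unadjusted p under 0.05, against 3222, and 1 to 177 genes by DESeq2, against 2104.

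The edgeR calls almost ended without hydrogel replicate 2 (7) or 3 (11). In both fits all 865 genes kept their direction and an unadjusted p under 0.05 (edgeR quasi-likelihood test). Over all genes tested, 2141 and 2276 had such a p, against 3222 with all 6 libraries. The smaller number of libraries alone cannot account for this, because at least 501 genes were called with any of the other libraries left out. The spread rose in these fits, with a biological coefficient of variation of at least 65.79% against at most 60.5% in the others, so a larger estimated spread is a candidate explanation. Hydrogel replicates 2 and 3 were the most alike pair, but differed by a mean chi-square of 31.34 per gene, where sampling alone would give about 1, which argues against 1 library deposited a second time. The design text calls the libraries of a group biological replicates. The counts cannot check whether hydrogel replicates 2 and 3 share an animal or a handling day.

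Blank replicate 1 held a higher level of genes high in hydrogel than the other blanks did, though a low one. Over genes chosen without it as near absent in the other blanks, its median level was 7.10% of the hydrogel level (428 genes), where the same choice made without blank replicate 2 or 3 gave 1.06% (303 genes) and 0.243% (243 genes). Those 2 sets are not the same genes, since they required blank replicate 1 to be near absent. Carry-over of 1 hydrogel library would give one share for all genes. Of 322 of the 428 genes with at least 10 counts expected, 13 (4.037%) had under 0.5 of the expected counts (Poisson p under 1e-06). Genes near 10 expected counts could not reach that p even with no read, so this share cannot decide. The quartiles of the level over the 428 genes were 4.33% and 12.3%. Carry-over stays open. For an exchanged label, blank replicate 1 correlated more with the other blanks (0.862 and 0.881) than with any hydrogel library (0.820 to 0.833), although its highest with a hydrogel library lay within 1 SD (0.0401) of the lowest between hydrogel libraries (difference -0.0304). The position of each left-out library from the blanks (0) to the hydrogel libraries (1), over the 500 genes with the lowest p in the fit without it, argues against an exchange. The median was 0.3766 for blank replicate 1, 0.200 and -0.20 for blank replicates 2 and 3, and 0.695 to 1.10 for hydrogel libraries (SD 0.228). The share of these genes nearer the hydrogel libraries was 22% in blank replicate 1, and 26% and 5.6% in blank replicates 2 and 3. More surviving or regrown epithelium in that animal may be a biological explanation and was not tested, since no cell type markers could be matched. The same holds for the main comparison: a different mix of cells in the tissue and regulation within cells cannot be told apart here.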
